A study of Mus musculus with 2 samples.

How the data were processed

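RNA of the mouse macrophage-like line RAW 264.7 was measured on 2 Agilent whole mouse genome arrays, 1 of cells labelled control and 1 of cells labelled RCCS, a rotary cell culture system used to model microgravity. Per the file headers, both arrays were scanned in 1 colour, lay at positions 1 and 2 of the same slide and were scanned together, so slide and scan do not separate the groups. Per the labels the dye was Alexa-555. The deposited spot values are intensities on a linear scale, which Agilent Feature Extraction 9.5.3.1 made from the scans per the file headers; the submitters' processing notes name the same software. Per the file headers, the processed signal had its background subtracted and its surface trend removed, and it was not scaled between arrays. A second table deposited by the authors holds a ratio per probe and array, with its scale, centring and direction unstated. Set against the scanner values, it is the processed signal divided by 849 on the control array and by 964 on the RCCS array, close to the 75th percentiles of 849 and 966, with a lowest value of 0.01. Each column is thus a signal relative to its own array, with no centring over genes and no direction between arrays. The median of that table was 0.06 in both columns, with 13287 and 13282 probes at the lowest value.

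The main value was log2 of the processed signal minus the array's 75th percentile of it over 41174 non-control probes, RCCS minus control. Spots of 1 probe were averaged first; 245 probes were printed 10 times. A probe counted as measured where it was well above background on at least 50% of its spots on both arrays. That share, and taking the percentile and this call over probes in place of spots, were set after a first run had been seen. Spots called outliers by the scanner software on either array were left out (117 spots on the control array and 120 on the RCCS array carried such a call), and 0 spots were saturated. A gene took the mean log2 ratio of its measured probes, and of 5091 genes with more than 1 measured probe, 371 had probes whose log2 ratios lay more than 1 apart. Accessions of 22951 probes matched a transcript of the mouse reference table of assembly GRCm38.p6 and took its symbol; the other 18223 probes kept the name in the file. That table was used for names alone, and no coordinates are given because the array's genome build is not given in the sources used here. List members found under an older name count under that name.

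With 1 array per condition no test between conditions can be made, so there is no p-value and no error between cultures, and every difference lacks a replicate check. Precision was taken from the spot error of the scanner software and from the probes printed 10 times. The median spot error of a gene's log2 ratio was 0.20, which gives a 95% half-width of 0.40 for a typical gene. This error is a value the software assigns, nearly constant at 0.204 for bright genes with 1 probe, and not a measured spread. Of the repeated probes, 151 were measured on 5 or more spots, and the SD of their log2 ratios had a median of 0.04 over 111 probes with a signal of 100 or more and 0.27 over 40 dimmer probes. Both cover spot error only, not cultures, RNA extraction or labelling.

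Genes at least 2-fold higher or lower were counted, and 33 gene lists were fixed before the data were examined, as were the groups, the alternatives and the rule for named genes. For each list the median log2 ratio was set against the medians of 10000 random lists of the same size, drawn from measured genes matched in 20 bins of mean log2 signal. That percentile describes these 2 arrays and is not a test. A gene well above background on 1 array only has a bound: its signal against the higher of the lowest signal among probes well above background on the other array and its own signal there, after scaling. Named in the text are the 12 highest and 12 lowest log2 ratios among 10307 genes with a regular symbol and a processed signal of at least 100 on the brighter array, the 5 largest bounds in each direction among genes with a regular symbol, up to 4 members of each list with the largest absolute log2 ratio (6 for the 3 osteoclast lists), and 20 genes fixed in advance (among them Csf1r, Tnfrsf11a, Nfatc1, Fos, Mitf, Acp5, Ctsk, Mmp9, Itgb3, Dcstamp, Ocstamp, Atp6v0d2, Oscar, Calcr, Irf8, S100a8, Il6, Tnf and Atg5). Some genes this rule takes and 1 of the lists are not reported here. Members of these lists and other genes named outside this rule were chosen after their values were seen.

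The alternatives were scaling at the median, at the 75th percentile of measured probes or on the spike-in probes, quantile normalization, loess scaling on signal, normexp background correction with an offset of 50 followed by 75th percentile scaling or by quantile normalization, the deposited ratio table, no filter on dim probes, a signal of at least 100 on the brighter array, the brightest probe of a gene, thresholds of 1.5-fold and 3-fold, a further filter on spot error, and 2 other rules for genes above background on 1 array. Limma 3.58.1 in R 4.3.3 gave normexp, quantile and loess values; Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 did the rest.

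The calculation was tested on simulated data for this comparison. A pair of arrays was drawn from the control array's values with the scanner software's spot error. It covered 16033 genes with a spot well above background on both arrays, and 50 genes each were changed by 1.5-fold, 3-fold, 4-fold and 8-fold. The 2-fold threshold took 0, 49, 50 and 50 of them, and 10 of 15833 genes left unchanged. The simulation held no trend with signal and no difference between cultures or labelling. Its 10 calls are therefore no estimate of false calls in the real comparison.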

Results

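The series asked how modelled microgravity alters gene expression in cells on the way to osteoclasts, the bone-resorbing cells that form from macrophage precursors under the cytokine RANKL. RAW 264.7, a mouse macrophage-like line that can become osteoclast-like, was loaded into the rotary cell culture system (RCCS) for 24 h, and RANKL was given at 80 ng/ml for 24 h. The control cells were kept at ground level in parallel. The protocol text is the same for both samples and leaves open whether the control cells also received RANKL, so a difference between the arrays is described as RCCS against control and nothing more. Each condition had 1 array. Of 41174 probes, 23693 (57.5%) were well above background on the control array and 24936 (60.6%) on the RCCS array, and 16023 genes were measured on both. Log2 signals of these genes correlated across genes between the arrays with a Pearson r of 0.978. Genes are not independent replicates, the number of arrays limits the precision, and no difference below has a replicate check.

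On the RCCS array 622 genes were at least 2-fold higher and 605 at least 2-fold lower than on the control array, together 7.66% of the genes measured. Of these, 118 were at least 4-fold higher and 78 at least 4-fold lower. The gene with the highest log2 ratio was S100a8, which encodes a calcium-binding protein of myeloid cells, at 6.17 (71.8-fold higher, processed signal 152 on the control array and 12449 on the RCCS array). It was followed by Stfa3, a stefin-type cysteine protease inhibitor, at 5.99, Pdpn, which encodes the membrane protein podoplanin, at 5.64, Prl2c5, of the prolactin family, at 5.53, and Hal, the histidine-degrading enzyme, at 5.52. The other genes of this group were Prss46 (5.08), the platelet chemokine Pf4 (4.90), Mcpt1 (4.56), Trem3 (4.29), the iron-siderophore carrier Lcn2 (4.05), Carmil1 (3.84) and Acsbg1 (3.81). Stfa3 and Prl2c5 belong to families of near-identical genes, so their probes may also have bound relatives. Stfa3, Pdpn, Prl2c5, Mcpt1 and Trem3 were dim on the control array, with processed signals of 27.6 to 39.4 where the lowest probe well above background had 23.9. With normexp background correction and 75th percentile scaling they came to 4.27, 4.17, 4.05, 3.14 and 2.78, and Carmil1 to 2.72. At the low end stood Oasl2 at -4.27 (19.3-fold lower, from 11774 to 693) and Isg15 at -4.23 (from 42335 to 2569). Gstt1, a glutathione transferase, was at -4.01, Ifi44l at -3.98, the chemokine gene Ccl5 at -3.73, Ifit3 at -3.56, the growth regulator Myc at -3.50, Isg20 at -3.48, Mx2 at -3.44, Apol9b at -3.35, Mc4r at -3.18 and Zbp1 at -3.13. Mc4r was dim on the RCCS array, with 225 on the control array and 28 there, and was at -1.81 at its nearest to 0 among the alternatives.

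The balance of higher and lower genes depends on the scaling. The median log2 ratio of all measured genes was -0.13, and 7 of the 10 spike-in probes, which were above background on both arrays, had a median of -0.31. Whether the spike-in amount per RNA mass was equal on both arrays is not given in the sources used here, so this scaling is an alternative with an unknown of its own. Scaled on these probes, the median of all genes moves up by 0.31, and 1190 genes are at least 2-fold higher and 262 lower, so that 82.0% of the calls are higher in place of 50.7%. With the 75th percentile of measured probes the counts were 833 and 416 (66.7% higher, median shift 0.14), with loess scaling 745 and 453 (62.2%, shift 0.11), and with normexp and quantile normalization 416 and 259 (61.6%). Without a filter on dim probes the median shifted by -0.12. Medians of lists are therefore also given relative to all measured genes, which a single scaling factor does not alter.

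**Figure D1:**
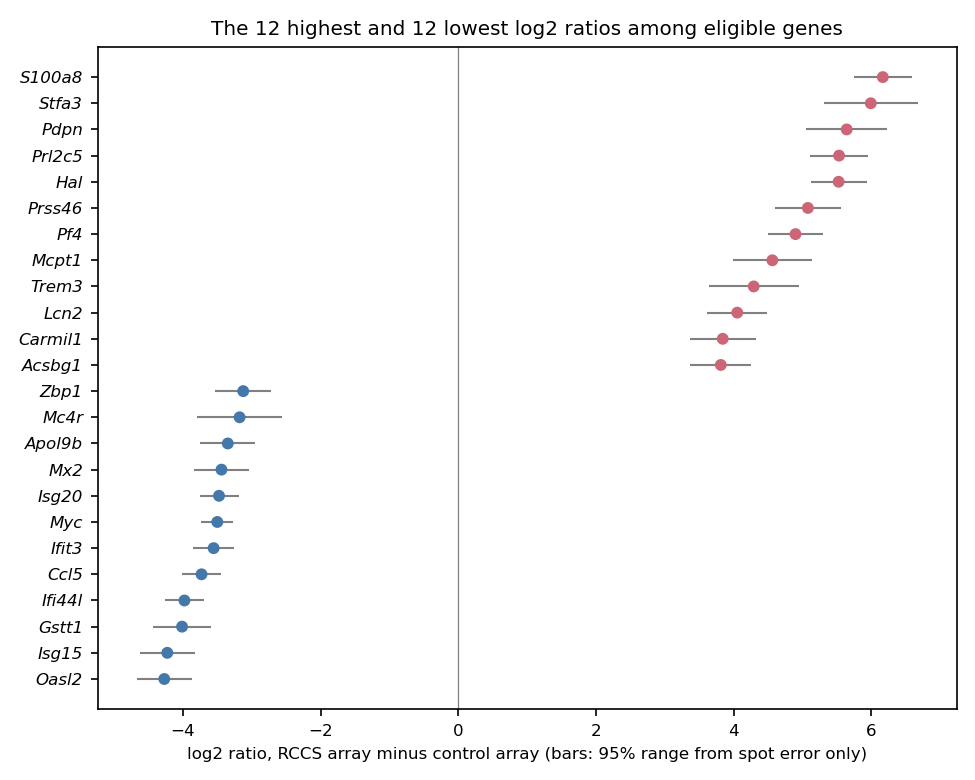
Log2 ratio, RCCS array minus control array, on the horizontal axis for the 12 genes with the highest (red) and the 12 with the lowest (blue) ratio, 1 gene per line; bars are 95% ranges from spot error only, with 1 array per condition. S100a8 stands at 6.17 and Oasl2 at -4.27.

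A further 1487 genes were well above background on the RCCS array only and 644 on the control array only, and 210 and 316 of them had a bound of at least 2-fold. The lowest signal called well above background was 19.9 on the RCCS array and 23.9 on the control array. The larger count on the RCCS array may thus come in part from dim signals and does not by itself show expression gained. Among genes with a regular symbol, the largest bounds on the RCCS side were those of Cstdc6, a stefin-family gene (at least 81.8-fold higher), the neutrophil-attracting chemokine Cxcl3 (at least 43.4-fold), the stefin Stfa2 (at least 26.7-fold), the collagenase Mmp8 (at least 26.5-fold) and Serpinb2, an inhibitor of plasminogen activators (at least 24.5-fold). On the control side they were those of Apod, which encodes apolipoprotein D (at least 10.4-fold lower on the RCCS array), the receptor kinase gene Ephb2 (at least 8.78-fold), Toporsl (at least 7.59-fold), Atf7ip2 (at least 7.12-fold) and Cdon (at least 6.74-fold). These control-side signals lay between 121 and 209.

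Interferon-response genes made up the group with the lowest median. All 42 measured members had log2 ratios below 0 and 40 were at least 2-fold lower on the RCCS array, with a median of -1.84 (3.58-fold lower; -1.71 relative to all genes) and 0 of 10000 random lists as low. The group held 6 of the 12 lowest genes named above. Among its other members, Irf7, the transcription factor that amplifies interferon production, was at -3.12, Mx1 at -2.84 and Ddx58, the RNA sensor RIG-I, at -2.76. Irf9 (-0.97) and Gbp2 (-0.66) were the members under 2-fold. Ifnb1, which encodes interferon beta, was not well above background on either array.

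Cytokine and chemokine genes went in both directions. Of 27 measured, 9 were at least 2-fold higher and 4 at least 2-fold lower, with a median of 0.20 (0.33 relative to all genes, above 99.97% of random lists). Ccl7, a monocyte attractant, was 13.6-fold higher, Ptgs2, the inducible cyclooxygenase, 9.80-fold higher and Cxcl14 9.20-fold higher, and Ccl5 was 13.3-fold lower. The others at least 2-fold lower were Cxcl11 (-2.56), Cxcl10 (-2.15) and Il15 (-1.69). Tnf had a log2 ratio of 0.99. Il6 was well above background on the RCCS array only and dim there (processed signal 58.9, at least 2.17-fold higher). Genes of signalling pathways and immediate early genes did not share 1 direction either. The NF-kappaB list had a median of -0.07, with Nfkbiz at 2.40 and Traf1, Nfkb2 and Birc3 at -2.18, -1.52 and -1.26. The list of MAP kinases and AP-1 kinases had a median of -0.07, with Mapk13 at 1.48, Pik3cb at 0.96, Map2k6 at -0.90 and Pik3cd at -0.80. The immediate early genes had a median of -0.21, with Dusp6 at 2.39, Atf3 at 1.35, Nr4a2 at -1.10 and Myc at -3.50. The medians of these 3 lists turn above 0 in 3 to 6 alternatives, and Birc3, Mapk13 and Nr4a2 came under 2-fold in at least 1.

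Osteoclast differentiation and fusion genes had a median of -0.13 over 33 measured members, 0.00 relative to all genes and above 75.2% of random lists; 3 alternatives put it above 0. The genes at least 2-fold lower were Jdp2, an AP-1 family partner (-2.02), Dcstamp, needed for fusion of precursors (-1.62), and Nfkb2 (-1.52). Itgav, an integrin subunit of the osteoclast's attachment receptor (1.29), and Jun (1.07) were at least 2-fold higher; without a filter on dim probes Itgav came to 0.45, and Jun came under 2-fold in at least 1 alternative. Atp6v0d2 and Ocstamp, both linked to fusion, were at -0.96 and -0.95. The probes of Ocstamp lay at -1.39 and -0.51. Other osteoclast genes fixed in advance lay nearer to 0, among them the RANK receptor gene Tnfrsf11a at -0.49, Nfatc1, the main transcription factor of osteoclast differentiation, at -0.57, Fos at -0.45, Mitf at 0.22, Itgb3 at -0.40, Oscar at -0.43 and Csf1r, the M-CSF receptor gene, at 0.05. Calcr was well above background on the RCCS array only, at a signal of 23.6, too dim to give a bound.

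Bone resorption and acid secretion genes had a median of 0.25 over 30 measured members, 0.38 relative to all genes, and 0 of 10000 random lists were as high. Ctsk, the collagen-cutting cathepsin of osteoclasts, was 2.33-fold higher (from 2225 to 5896), and Plekhm1 (1.04) and Ostm1 (1.01), which act in lysosome transport and chloride exchange, were at least 2-fold higher. The proton pump subunits Atp6v1a (0.93) and Atp6v1d (0.89) came next. Slc9b2, a sodium-proton exchanger, was at -1.22; it and Ostm1 came under 2-fold in at least 1 alternative. Acp5, the tartrate-resistant acid phosphatase used as an osteoclast marker, was at 0.06, and Mmp9 at -0.66, with its probes at -1.23 and -0.08.

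The list set in advance as brakes on osteoclast differentiation had 30 measured members, 8 at least 2-fold higher and 4 at least 2-fold lower. Its median was 0.14 (0.27 relative to all genes, above 99.8% of random lists). Whether each member acts as a brake in these cells was not tested. Id1 was 13.8-fold higher (from 370 to 5800), Socs3 5.07-fold, Id2 3.84-fold, Tlr4 at a log2 ratio of 1.60 and Irf8 at 1.14. Without a filter on dim probes Tlr4 came to 0.23. Irf1 (-1.12), also a member of the interferon list, Socs1 (-1.15) and Rcan1 (-1.02) were among those at least 2-fold lower.

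**Figure D2:**
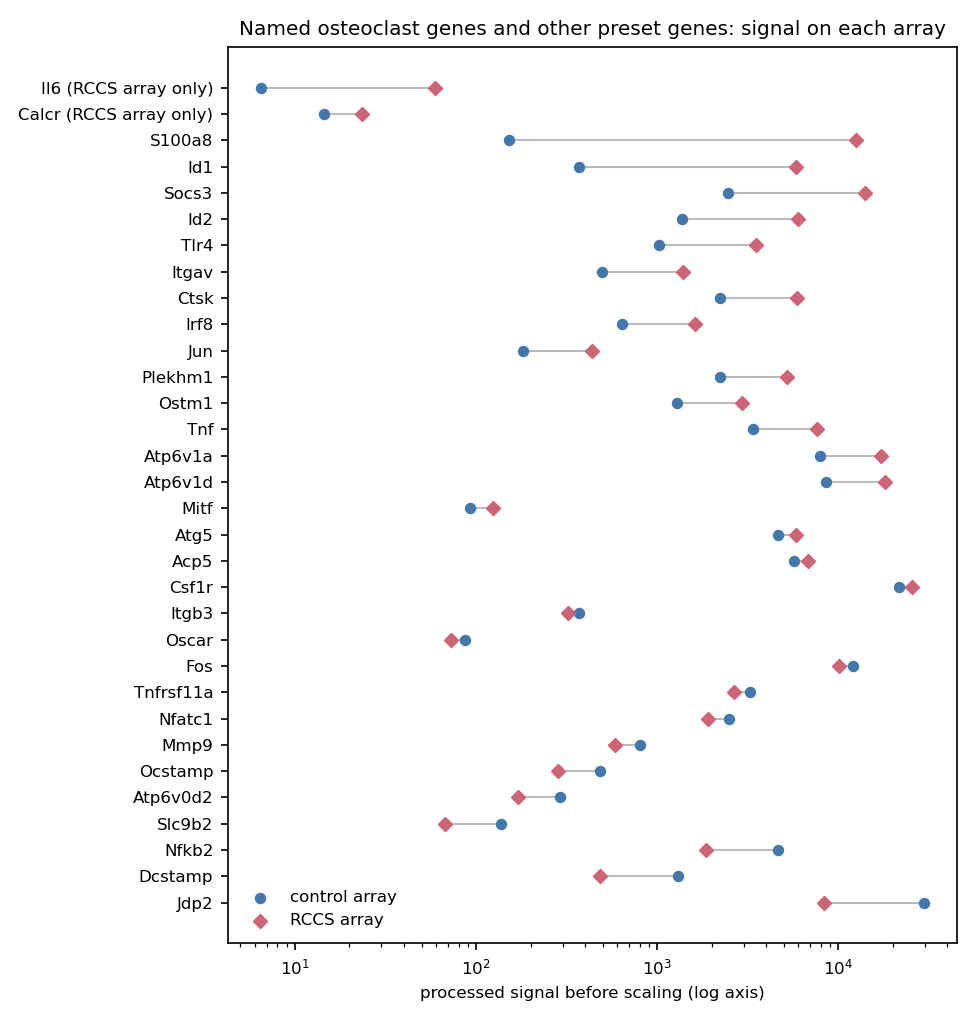
Processed signal before scaling (horizontal log axis) of named osteoclast genes and genes fixed in advance, 1 gene per line, on the control array (blue circles) and the RCCS array (red diamonds), ordered by log2 ratio with genes measured on 1 array only at the top. Jdp2 and Dcstamp stand at the bottom with log2 ratios of -2.02 and -1.62, and Id1 near the top with 3.78.

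Cathepsins, matrix proteases and cystatins had the highest median of the 33 lists, 0.57 over 31 measured members (0.70 relative to all genes, 0 of 10000 random lists as high). Mmp12, the macrophage elastase, was 10.1-fold higher and Ctsl was at 1.26, from 72289 to 197041. A further 5 members, Mmp8, Mmp10, Mmp13, Serpinb2 and Stfa2, were well above background on the RCCS array only. Of these, Mmp10 was near background there (signal 27.6, at least 1.02-fold higher) and Mmp13 was dim (67.0, at least 2.47-fold). Cst7 (-1.07) was the member at least 2-fold lower. Among S100 and other calcium-binding protein genes the median was 0.05, and S100a8 and Anxa3 (2.52, or 1.06 without a filter on dim probes) were at least 2-fold higher. S100a3 was at -0.82 and Anxa6 at 0.76. S100a9, whose product pairs with that of S100a8, was not well above background on either array (10.9 and 12.2). Calcium signalling genes had a median of 0.02, which 1 alternative puts below 0, with the inositol trisphosphate receptors Itpr3 (1.21) and Itpr2 (1.10, and 0.80 at its lowest among the alternatives) highest, followed by Orai2 (0.65) and Nfatc3 (-0.65). The 4 probes of Itpr2 spread from 0.45 to 1.54 and the 3 of Nfatc3 from -1.38 to 0.08.

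Macrophage receptor genes had 11 of 38 measured members at least 2-fold higher and 3 at least 2-fold lower, with a median of 0.27 (0.40 relative to all genes, 0 of 10000 random lists as high). The lectin receptor Clec4n was 11.5-fold higher, and the Fc receptors for IgG Fcgr2b and Fcgr3 were 6.78-fold and 5.41-fold higher. H2-Ab1, of the class II antigen-presenting complex, was at -2.51, with probes at -3.21 and -1.80 and a value of -1.33 after normexp and quantile normalization, and Cd40 (-1.98) and C1qb (-1.26) were the others at least 2-fold lower. Integrin and adhesion genes had a median of 0.03 and 5 members at least 2-fold higher. Itgb7 was at 3.56, Itgb5 at 2.63, Itgal at 2.05, and Itgam went from 1125 to 5116; the fifth was Itgav. Lgals9, which encodes a galectin, was at -1.15. The 47 measured actin and podosome genes had 0 members at least 2-fold higher or lower and a median of 0.06 (0.19 relative to all genes, 0 of 10000 random lists as high), with Actn1 (0.83), Zyx (0.81), Myh9 (0.79) and Myo1f (0.65) highest. Myh9 came to 0.17 at its lowest among the alternatives. Of 25 tubulin and intermediate filament genes, 7 were at least 2-fold lower, among them the lamin genes Lmnb1 (-1.71) and Lmnb2 (-1.16) and the beta-tubulins Tubb4a (-1.28) and Tubb4b (-1.20). Lmnb2, Tubb4a and Tubb4b came under 2-fold in at least 1 alternative. The list median, -0.25, ran from -0.71 to 0.06 over the alternatives, and tubulin probes may bind related tubulins.

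Cell cycle genes were lower on the RCCS array nearly without exception. Of 43 genes of G1 and S phase, 41 had log2 ratios below 0 and 11 were at least 2-fold lower, with a median of -0.87 (-0.74 relative to all genes). The members above 0 were the cyclin gene Ccnd2 (0.37) and Cdkn1a (0.21), an inhibitor of the cycle. Cdk6 was at -1.44, the replication factors Mcm10 and Mcm7 at -1.27 and -1.20, and the thymidine kinase Tk1 at -1.25. Of 45 genes of G2 and mitosis, all were below 0 and 13 at least 2-fold lower, with a median of -0.90 (-0.77 relative to all genes). Examples were Top2a (-1.28), Anln (-1.27), Kif2c (-1.26) and Plk1 (-1.25). For each list, 0 of 10000 random lists were as low. The probes of Cdk6 spread from -1.86 to -0.95 and those of Top2a from -1.86 to -0.70. Each of the genes named here as at least 2-fold lower came under 2-fold in at least 1 alternative.

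Cholesterol and fatty acid synthesis genes formed the other group outside the random range at the low end. Of 40 measured, 37 were below 0 and 9 at least 2-fold lower, with a median of -0.58 (-0.45 relative to all genes, 0 of 10000 random lists as low). The desaturases Scd1 and Scd2 were 3.82-fold and 3.26-fold lower, and Insig1, a sensor of the sterol pathway, 2.76-fold lower. Abca1, which exports cholesterol and belongs to the same list, was 3.62-fold higher; Fdft1 (0.51) and Nr1h3 (0.41) were also above 0.

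Genes of the oxidative stress response had 4 members at least 2-fold higher and 1 lower among 37 measured, with a median of 0.13 (0.26 relative to all genes, 0 of 10000 random lists as high). Slc7a11, the cystine importer, was 8.47-fold higher, Hmox1, which degrades heme, 6.13-fold (from 10255 to 71552), Gstp1 at 1.52 and Cat, which encodes catalase, at 1.27. Keap1, the inhibitor of NRF2, was the member at least 2-fold lower (-1.07). In the amino acid and unfolded protein stress list the median was -0.31, and 1199 of 10000 random lists were as low. Apart from Slc7a11 and Atf3, its named members were lower, with Cth at -1.67 and Mthfd2 at -1.30. Heat shock and chaperone genes had a median of -0.30, above 30.2% of random lists and above 0 in 1 alternative, with Fkbp4 (-1.29), Hspb1 (-1.03), Hspa8 (-0.80) and Hsp90ab1 (-0.68). Hypoxia and glycolysis genes had a median of -0.12, above 0 in 5 alternatives, with Eno2 (1.87), Ndrg1 (1.57), Vegfa (1.12) and Slc2a1 (0.69). At their nearest to 0 among the alternatives, Hspb1 was at -0.29, Vegfa at 0.66 and Eno2 at 0.95, and Fkbp4 and Mthfd2 also came under 2-fold.

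Autophagy genes had a median of 0.10 over 33 measured members (0.23 relative to all genes, above 99.2% of random lists). Rb1cc1 (1.02) was the member at least 2-fold higher. Sqstm1 stood at 0.92, Atg7 and Map1lc3a at 0.67 and Atg5 at 0.16. Atg7 came to 0.13 at its lowest among the alternatives. The p53 target list had a median of 0.19, above 99.9% of random lists, with Pmaip1 at -1.25, Trp53inp1 at 1.09, and Aen and Gadd45b both at -0.74. Apoptosis genes had a median of -0.12, above 0 in 3 alternatives, with the TNF receptor gene Tnfrsf1b (1.53) and the survival gene Bcl2l1 (1.31) higher and Birc3 (-1.26) and Pmaip1 lower. The probes of Tnfrsf1b lay at 0.70 and 2.35. Rb1cc1, Trp53inp1, Pmaip1 and Birc3 came under 2-fold in at least 1 alternative.

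**Figure D3:**
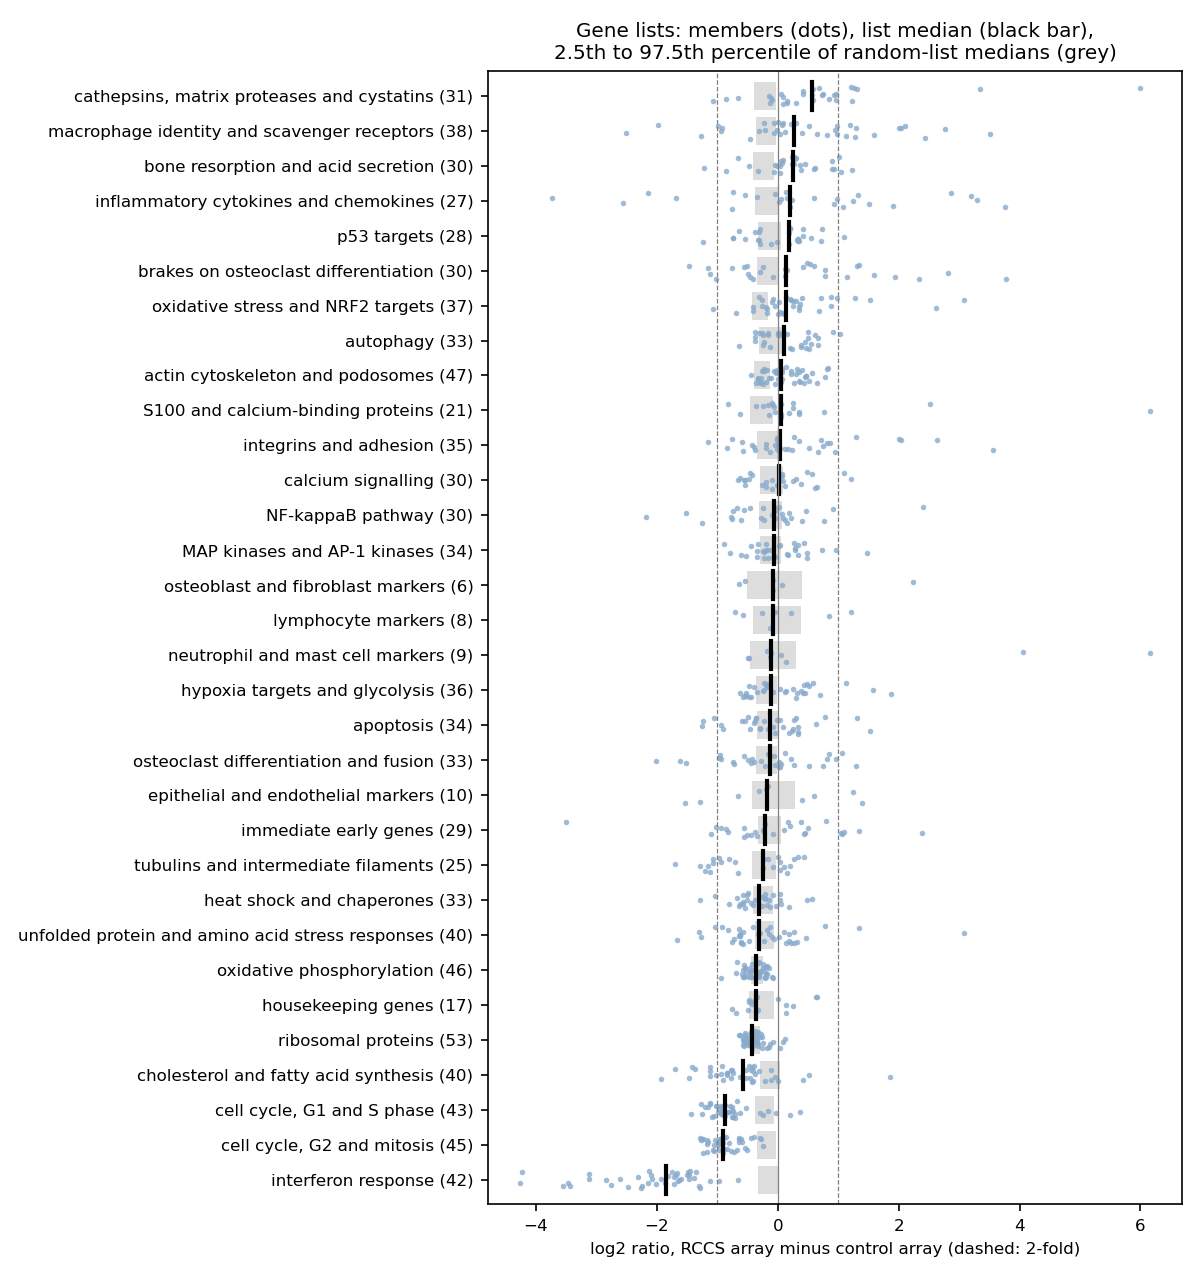
Log2 ratio, RCCS array minus control array (horizontal axis), of the measured members of 32 gene lists (blue dots), with the list median (black bar), the central 95% of the medians of 10000 random lists (grey) and the number measured in parentheses. The interferon list lies lowest with a median of -1.84 and the cathepsin list highest with 0.57; 4 of these lists lie below the grey range and 11 above it.

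Bright gene families lay below 0 without leaving the random range. The median was -0.42 for 53 ribosomal protein genes (above 9.78% of random lists, and 0.01 after loess scaling), -0.35 for 46 genes of oxidative phosphorylation (48.8%) and -0.36 for 17 housekeeping genes (28.2%), and 0 of these were at least 2-fold higher or lower. The largest values were those of Rpl3 (-0.64), Rpl14 (-0.62), Rpl28 (-0.58) and Rpl10a (-0.57), of Ppargc1b (-0.93), Cyc1 (-0.69), Uqcrfs1 (-0.67) and Ndufa10 (-0.59), and of B2m (-0.76), Eif4a2 (0.65) and Tfrc (0.64). Over 8 equal bins of signal the median log2 ratio rose from -0.18 in the dimmest bin to -0.02 in the fourth and then fell to -0.34 in the brightest.

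Marker genes of other cell types were mostly dim or not measured. Of 22 osteoblast and fibroblast genes 6 were measured, with Runx2 at 2.23, Col5a1 at -0.64, Col1a2 at -0.55 and Sparc at -0.08. A further 6 were well above background on the RCCS array only and 1 on the control array only. Dcn, which encodes the fibroblast matrix protein decorin, was well above background on the RCCS array only, at a signal of 462 (at least 17.0-fold higher). Of 24 lymphocyte genes 8 were measured, with Cd3g at 1.21, Cd79a at 0.86, Cd3e at -0.70 and Lck at -0.57. Of 19 neutrophil and mast cell genes 9 were measured, and a further 3 were well above background on the RCCS array only and 0 on the control array only. S100a8 and Lcn2 were higher as given above, and Cxcr2 (-0.49) and Fcer1a (-0.47) came next in size. Of 20 epithelial and endothelial genes 10 were measured, with Epcam at -1.54, Vwf at 1.40, Krt5 at -1.28 and Eng at 1.25. At their nearest to 0 among the alternatives, Runx2 was at 0.99, Cd3g at 0.41, Epcam at -0.59, Vwf at 0.61 and Krt5 at -0.78, all under 2-fold.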

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

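With 1 array per condition no replicate could be left out, and no paired analysis was possible because the results come from no test. A list median counted as moved when it shifted by more than the median spot error, 0.20. Of 33 lists, scaling on the spike-in probes moved 33, loess scaling 11, normexp with quantile normalization 7 and quantile normalization 4. A signal of at least 100 on the brighter array moved 3, and the brightest probe of a gene moved 1. Of 106 named genes at least 2-fold higher or lower, 0 changed sign in the 11 alternatives that give log2 ratios, and 36 came under 2-fold in at least 1. The overall median shifted by at most 0.31 in these alternatives. Genes picked at 2-fold could therefore hardly change sign, and the 0 says little about their stability. Medians of the interferon, cell cycle, cholesterol, cathepsin, bone resorption and brakes lists kept their sign in these 11 alternatives. That of osteoclast differentiation, -0.13, turned to 0.18 on the spike-in probes and was above 0 in 3 alternatives. Among other lists whose sign turned were MAP kinases in 6 alternatives, hypoxia in 5 and ribosomal proteins in 1.

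Scaling on the spike-in probes gave 1190 genes at least 2-fold higher and 262 lower, and shifted every list by construction, to 0.56 for bone resorption, 0.44 for the brakes, -1.54 for interferon response, -0.56 for G1 and S phase, -0.60 for G2 and mitosis and -0.27 for cholesterol and fatty acid synthesis. Loess scaling gave -0.65 for G1 and S phase. Normexp with 75th percentile scaling gave 710 genes at least 2-fold higher or lower (363 and 347), and with quantile normalization 675 (259 lower), with -1.53 for interferon response and -0.70 for G2 and mitosis; the offset pulls ratios of dim probes toward 0. Without a filter on dim probes there were 3413 genes (1607 higher, 1806 lower) among 28783, more because dim probes enter. Thresholds of 1.5-fold and 3-fold gave 3939 (1560 and 2379) and 359 (205 and 154). Of genes well above background on 1 array, 210 on the RCCS array and 316 on the control array were at least 2-fold above the bound, so signal near background limits most of that group. Where no cause is given, the cause was not tested.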

Other observations

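Several genes outside the rule for named genes stood out and were chosen after their values were seen. Among genes well above background on the RCCS array only were a further stefin gene, Stfa2l1 (at least 7.54-fold higher), and the platelet-type gene Ppbp (at least 8.27-fold). Csf3, which encodes a growth factor that acts on granulocytes, was on that array only as well (at least 15.9-fold higher). Arg1, the arginase of alternatively activated macrophages, was at least 7.39-fold higher, the quinone reductase Nqo1 at least 5.81-fold and Smad7, an inhibitor of TGF-beta signalling, at least 10.9-fold.

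The tests below that concern array scaling and inflammatory stimulation for the interferon genes, and neutrophils for S100a8, were chosen only after the result was seen. The low interferon-response genes could come from the scaling, and the list median was at most -1.53 over the scaling and background alternatives. These alternatives shift the median of all genes by at most 0.31, so that outcome was nearly fixed in advance and decides little. A single scaling factor, however, leaves the list's median relative to all genes at -1.71, so such a factor cannot account for it. A local artefact on the array surface is argued against too, since the medians in the 4 quadrants of the array were at most -1.61, while all measured spots there had medians from -0.14 to -0.10. If the control culture had met an inflammatory stimulus such as endotoxin, the cytokine genes it drives would be lower on the RCCS array as well; 8 of 11 such genes were measured, all 8 were above 0, and their median was 1.45 (SD 1.51). Other genes such a stimulus drives went both ways, with Traf1 at -2.18, Cd40 at -1.98, Nfkb2 at -1.52 and Birc3 at -1.26 but Nfkbiz at 2.40, and the NF-kappaB list had a median of -0.07 with 12 of 30 members above 0, so it stays open. That the RCCS condition itself lowered interferon signalling stays a hypothesis, because 1 culture per condition cannot separate it from an interferon response that arose in the control culture for another reason, and a different RANKL exposure stays open as well.

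The low cell cycle genes may reflect the trend by which log2 ratios fell with signal among the brighter genes. After loess scaling, which removes that trend, the median of the 88 measured cell cycle genes was -0.68 (-0.90 before), while that of the ribosomal protein genes went to 0.01, so the trend does not account for the cell cycle genes as a whole. Slower division in the RCCS culture, or a difference in cell density between the cultures, was not tested.

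S100a8, Lcn2 and Mmp8 are abundant in neutrophils, so another cell type in the RCCS culture (neutrophils) is a candidate source. Of 10 other abundant neutrophil and granulocyte genes, 2 (Ngp and Csf3r, at signals of 29.0 and 50.9) were well above background on the RCCS array only, 0 were measured as at least 2-fold higher, and 5 were not well above background on either array, S100a9 among them. Whether neutrophils at every stage of maturation carry all 10 at high levels was not examined, so this count alone does not decide the question. The lack of S100a9 signal, whose product pairs with that of S100a8, speaks against neutrophils as the source of S100a8. The count of 10 genes points the same way, with 2 on the RCCS array only, both dim, and 0 at least 2-fold higher. Together these values argue against neutrophils as the source of S100a8. Neutrophils are not excluded, since the test was chosen after the result was seen. What raised the few genes was not tested.

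A pair of hypotheses was tested on lists written after the data were first examined but before their own values were seen. Id1, Id2 and Id3 (1.34) were higher on the RCCS array, and they are targets of SMAD signalling downstream of BMP and TGF-beta. A list of other SMAD targets had 12 measured members with a median of 0.39 (0.52 relative to all genes, above 99.5% of random lists, and between 0.24 and 0.70 over the alternatives), with Smad6 at 1.91 and Skil at 1.36. That median leaves out 1 member well above background on the RCCS array only, and 0 members were so on the control array only. The median needed for this idea had been set at 0.5 and that against it at 0.2, so the list leaves it open. The high cathepsin and acid-pump genes may be part of a broader set of lysosomal genes. A list of 29 other lysosomal genes, none of them in the cathepsin or resorption lists, had 27 members above 0 and 4 at least 2-fold higher, with a median of 0.45 (0.58 relative to all genes, 0 of 10000 random lists as high, and between 0.37 and 0.76 over the alternatives), past the 0.3 set in advance. Gla (1.12) and Sgsh (1.10) were among the highest, and Npc2 was at -0.71. Tfeb, a transcription factor of lysosomal genes, was at -0.30. As with the rest, this holds for a single pair of cultures.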
